A study of Drosophila melanogaster with 3 samples.

How the data were processed

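Nascent RNA was measured by global run-on sequencing (GRO-seq), in which engaged RNA polymerases extend their transcripts in isolated nuclei and the labelled RNA is sequenced, so that reads mark transcribing polymerase and not stored RNA. The cells were untreated SL2 cells, an embryo-derived Drosophila line with a male type of dosage compensation. The 3 libraries form 1 group with 2 biological replicates, per the labels. Replicate 1 was sequenced in 2 lanes and replicate 2 in 1 lane.

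The deposited files list aligned reads of 36 bases, 1 line per read, with arm, strand and leftmost position. Bowtie and the dm3 build are named in the submitters' processing notes, and the version of Bowtie is not given in the sources used here. The alignments were not processed alike between replicates. The deposited files of replicate 1 hold reads with up to 10 mismatches, and 5.20% and 5.04% of the reads in its lanes had more than 2. The deposited file of replicate 2 holds no read with more than 2. The share of reads without a mismatch was 53.0% and 53.5% in the lanes of replicate 1 and 70.5% in replicate 2. Only 33, 35 and 24 reads of the libraries had another place reported in the files. Whether other reads had further possible places that were not reported was not tested.

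The plan made before the data were examined was to measure annotated genes. No annotation or sequence of dm3 was used here, and coordinates were not converted between builds, so transcription units were called from the reads. Measures per annotated gene, the 18 gene lists fixed in advance, exon against intron density, mappable length and a filter on annotated starts were not analysed here. Units carry no gene names, and a unit may hold part of a gene or more than 1 gene. The tests, measures and thresholds were kept as planned, with units in place of genes and 5000 bp windows in place of genes for the share that was transcribed.

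Read 5′ ends of all libraries were pooled per strand in bins of 200 bp and smoothed by a running median over 5 bins. Each bin was given a background level of 0.05 reads or 1 of 12 levels that double from 1 read, by a Viterbi path with negative binomial emissions of size 3 and a log cost of -8 for each change of level. A change of more than 2 doublings from the preceding level ended a unit. The start was moved by up to 500 bp to the sharpest rise between adjoining windows of 100 bp, a choice that favours dense promoter-proximal windows. Units entered the comparisons if they were at least 2500 bp long, had at least 50 body reads in each replicate and lay at least 500 bp from the end of the unit upstream on the same strand. The X was compared with the 4 large autosomal arms, and chromosome 4, Y, heterochromatic and unplaced sequence stayed outside the comparisons.

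The settings of this caller were not blind to the outcome. X and autosomal medians had been seen under 5 settings of an earlier 2-state caller, which joined neighbouring units into stretches of up to 715560 bp, and under 5 settings of the level model. The level model's setting used here was the first one written. A rule that compares each level with all earlier levels of a unit was added as an alternative after results had been seen. All of these settings are among the alternatives.

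The promoter-proximal window was the first 500 bp of a unit and the body ran from 500 bp after the start to 500 bp before the end. Unit density was the number of sense reads per kb per 1000000 sense reads in units (RPKM), with 1 read added to each count, on the log2 scale. The pausing index was the log2 ratio of promoter-proximal to body density. The elongation density index was the log2 ratio of density in the downstream 75% of the body to that in the upstream 25%. A unit was called paused where a one-sided Fisher's exact test of reads per base had a Benjamini-Hochberg adjusted p below 0.05 and the density ratio was at least 2, in both replicates. A window was called transcribed where a Poisson test against reads at least 5000 bp from any unit gave an adjusted p below 0.01 in both replicates.

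Differences of medians were tested by two-sided permutation tests over units with 100000 resamples and shares by two-sided Fisher's exact tests, and the 5 unit-level p-values were adjusted by the Benjamini-Hochberg method. Confidence intervals of 95% came from 2000 bootstrap draws of units. Units are not replicate samples and neighbours may depend on each other, so contiguous runs of 308 autosomal units served as a second reference. Errors are SD over the 2 replicates. The named units followed a rule fixed before the data were examined: the 10 X-linked and 10 autosomal units with the highest body density, the 10 most paused and the 5 with the lowest pausing index, and the 5 highest and 5 lowest X-linked units in elongation density index with at least 200 body reads in each replicate.

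The scripts were tested on simulated data, in which 9365 units took their density and pausing index from autosomal units of similar length. With no planted difference, the X minus autosome body density averaged 0.016 ± 0.061 (SD over 10 draws) and none of the 10 passed the permutation test, and the elongation density index averaged -0.0021 ± 0.033, with 2 of the 10 draws past the threshold. An earlier simulation of single draws, made with the alternative rule for ending units and with densities drawn regardless of length, had given a lower X body density past the threshold with none planted, and it was replaced. In 10 new draws regardless of length under the rule used here, the body difference averaged -0.027 ± 0.046 (SD) with 1 past the threshold, and the elongation density index passed in 3. The cause of the earlier result was not found. A planted body difference of -0.4 was recovered as -0.35, a planted pausing index difference of -0.4 as -0.22 and a planted elongation density index difference of 0.3 as 0.25, each the mean of 5 draws. The simulated sets were larger (medians of 2547 units in the draws matched on length and 3643 in those regardless of length, both without a planted difference, against 1736 in the data), and the index varied less over draws than its bootstrap standard error of 0.084 in the data, so they do not measure the power of the comparison. Without a planted difference, 95.9% of unit starts lay within 100 bp of a simulated start in the draws matched on length. The share was 97.5% in those regardless of length. Simulated units took their starts from units called in the data and were densest in their first 100 bp. The search for the sharpest rise favours such starts, so these shares do not measure the accuracy of starts in the data. Reads carried no molecular identifiers, so repeated reads at 1 position may be copies of 1 molecule.

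Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. The alternatives covered read and length minima, collapsed reads, window sizes, single replicates, lanes and autosomal arms, GC content and length, unit calling and the mismatch limit.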

Results

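GRO-seq reads were obtained from untreated Drosophila SL2 cells in 2 biological replicates. Replicate 1 gave 3512796 and 3636906 aligned reads in its 2 lanes, and replicate 2 gave 3528484. The number of distinct stranded 5′ end positions was 65.3%, 64.9% and 62.4% of the number of reads, in that order. Over 16579 strand-specific windows of 5000 bp with at least 20 reads, the 2 lanes of replicate 1 differed by no more than sampling noise (chi-square per degree of freedom 1.001, p = 0.446). They were summed and counted as 1 replicate. The replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.03, and their window counts had a Spearman correlation of 0.927 and a Pearson correlation of log2 counts of 0.968 across windows, which are not independent replicates.

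The first comparison asked how much nascent transcription the X carried relative to the autosomes, in a line whose male-type dosage compensation is the subject of the series. The X had the lowest read density of the large arms. It held 5.85 ± 0.115 reads per kb of arm per 1000000 reads of the library (RPKM; SD, n = 2). Arm 3R held 9.58 ± 0.044, arm 2L 9.14 ± 0.115, arm 2R 8.78 ± 0.032 and arm 3L 7.37 ± 0.042. The X density was 0.669 ± 0.014 of that of the pooled autosomal arms, with 0.679 in replicate 1 and 0.659 in replicate 2. The corresponding ratios of the autosomal arms were 1.05 for 2L, 1.004 for 2R, 0.843 for 3L and 1.10 for 3R. The gap between the X and each autosomal arm was larger than the spread between replicates. These are densities per cell population without a measure of DNA copy number, so they are not per gene copy.

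**Figure D1:**
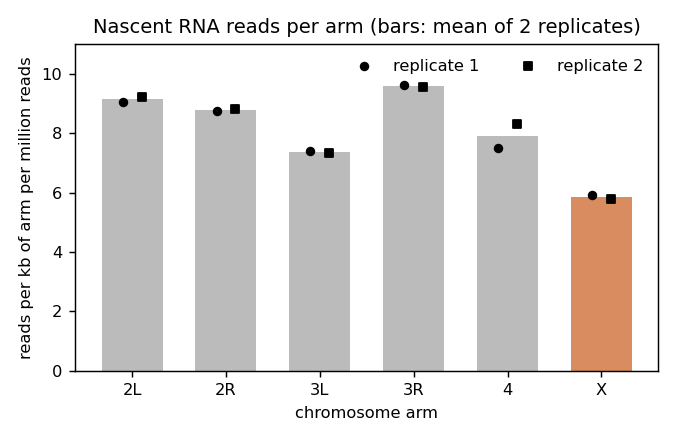
Read density of each chromosome arm, in RPKM over the length of the arm. Bars are means of 2 replicates and points are the replicates; the X, at 5.85, lies below every other arm shown.

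The lower density of the X did not come with a smaller transcribed part of the arm. Of 4485 X windows of 5000 bp, 2419 were transcribed (53.9%), against 10176 of 19319 autosomal windows (52.7%). The difference of 1.26 percentage points did not pass the two-sided Fisher's exact test (p = 0.131). Among the autosomal arms the share ran from 49.1% on 3L to 56.9% on 2R. Without replicate 2 the difference was 1.64 points and passed Fisher's exact test (p = 0.0459), and with a minimum of 1 RPKM it was -0.88 points.

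A total of 12155 transcription units were called, 2072 on the X and 10083 on the autosomal arms, and they held 97.1% and 96.8% of the reads of replicates 1 and 2 on these arms. The length and read minima were met by 4332 units, and the distance from the unit upstream reduced these to 1736. This compared set had 308 units on the X and 1428 on the autosomal arms. Its median length was 7996 bp on the X and 6872 bp on the autosomes. The median unit had 432 body reads in replicate 1 and 210 in replicate 2. The densest 100 bp of the first 500 bp lay at the start in 85.1% of units, and starts had been placed at the sharpest rise.

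Polymerase density in the bodies of X-linked units was lower than in autosomal units. The median body density was 3.11 on the X and 3.55 on the autosomes on the log2 scale, a difference of -0.44 or a fold of 0.736 (95% interval 0.637 to 0.803). The difference was -0.48 in replicate 1 and -0.44 in replicate 2. The permutation test over units gave p = 1e-05, the smallest it can give, and an adjusted p of 2.5e-05. Medians of the autosomal arms lay between 3.405 on 3L and 3.71 on 3R, and contiguous runs of 308 autosomal units differed from the rest by -0.21 to 0.24. Shifting the run along the autosomes in place of the X, as a permutation of position, gave p = 0.0007 for the X difference, the smallest it can give. The 1428 runs overlap heavily and are not independent, so this p-value may be too small. Without a minimum of body reads the difference was -0.70.

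Among single units, the densest on the X covered 1371880 to 1377323 of dm3 on the minus strand, with 135.3 ± 14.6 RPKM of sense reads (SD, n = 2) and a pausing index of 1.77 ± 0.19. The next X-linked unit, at 15721280 to 15729183 on the minus strand, had 60.6 RPKM, and the 10 densest X-linked units ran down to 28.8. The densest autosomal unit lay at 21677080 to 21681981 of 2L on the minus strand, with 257 RPKM. It was followed by a unit at 16948611 to 16951600 of 3L on the plus strand with 167. The 10 densest autosomal units ran down to 100.8, and 4 of them lay on 3R, 3 on 3L, 2 on 2L and 1 on 2R. They came from 1428 units and the 10 on the X from 308, so the ranges do not cover like shares of each group. Of these densest units, 6 on the X and 4 on the autosomes were called paused.

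**Figure D2:**
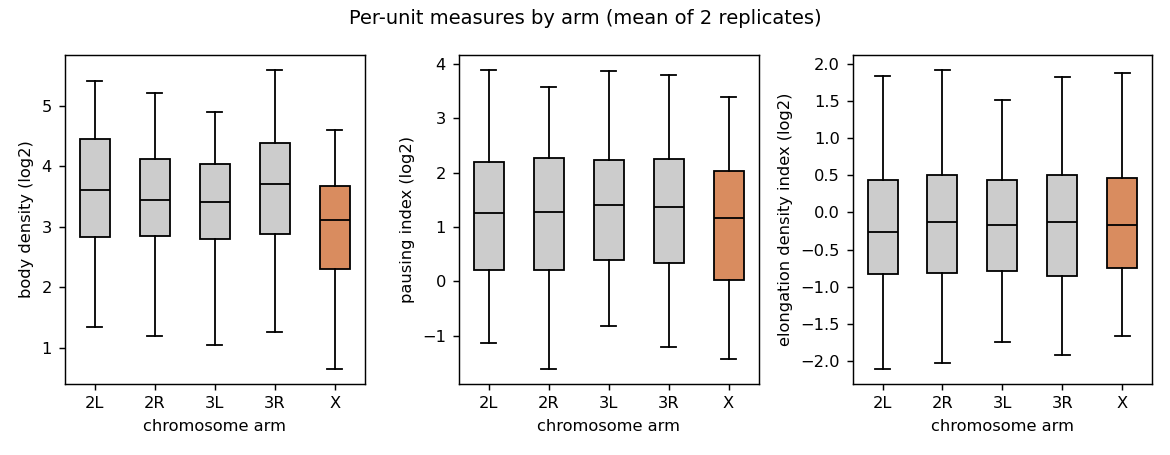
Body density, pausing index and elongation density index of the units in the compared set by chromosome arm, on the log2 scale and averaged over 2 replicates. Boxes give medians and quartiles and whiskers the 5th to 95th percentiles; the X median of body density, 3.11, lies below those of the autosomal arms, and the medians of the elongation density index lie close together.

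Promoter-proximal density, which reflects polymerase just after initiation, was also lower on the X. The median was 4.20 on the X and 4.95 on the autosomes, a difference of -0.74 or a fold of 0.597 (95% interval 0.490 to 0.700). It was -0.71 in replicate 1 and -0.77 in replicate 2. The permutation test gave p = 1e-05, the smallest it can give, and an adjusted p of 2.5e-05. With units close to an upstream unit kept, the difference was -0.49. With the 2-state caller, which draws longer units, the difference stayed negative under 5 settings (-0.66 to -0.34) but passed the test under 2 of them.

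Paused polymerase was common on all arms, and no difference between X and autosomes passed the test in the pausing index. Its median was 1.17 on the X and 1.32 on the autosomes, a difference of -0.15 (95% interval -0.39 to 0.052, permutation p = 0.212, adjusted p = 0.353). In simulations a planted pausing index difference of -0.4 was recovered as -0.22, so the value here may understate a difference. With 0.3 planted in the elongation density index, the mean pausing index difference was -0.20, which passed the test in 3 of 5 draws. Over all 5 draws the mean body density difference was 0.12 and the mean promoter-proximal density difference was -0.17. The index was therefore not the only measure that shifted, so these draws do not show the effect of a gradient alone. Paused units made up 153 of 308 X-linked units (49.7%) and 758 of 1428 autosomal units (53.1%; Fisher's exact p = 0.285, adjusted p = 0.357). This difference of -3.41 points passed Fisher's exact test with reads at 1 position collapsed (-6.48, p = 0.0474), with unit ends at level changes of more than 3 doublings (-7.98, p = 0.00429) and with units called in replicate 1 and measured in replicate 2 (-7.26, p = 0.0136). The autosomal arms ranged from 51.04% on 2L to 53.9% on 3L. The difference in the pausing index passed the test as a difference of means (-0.24, permutation p = 0.0128) and in a linear model with length and GC content (-0.29, permutation p = 0.0038). It also passed with level changes of more than 3 doublings (-0.35, permutation p = 0.00515), so the call depends on the measure and on unit calling. It was 0.20 and 0.012 under 2 settings of the 2-state caller. With units close to an upstream unit kept, the difference in the pausing index was -0.017.

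The most paused unit lay at 14389080 to 14409547 of 2L on the minus strand, with a pausing index of 7.22 ± 0.65 (SD, n = 2). It was followed by units at 8820607 to 8840200 and 9756641 to 9782800 of 3L on the plus strand, with indices of 6.83 ± 0.077 and 6.50 ± 0.11. The 10 most paused units ran down to 5.38, with 4 on 3R, 2 on 3L, 2 on the X, 1 on 2L and 1 on 2R. The X-linked units among them covered 409480 to 417255 on the minus strand, with 5.47 ± 0.30, and 8303295 to 8329000 on the plus strand, with 5.38 ± 0.21. The 5 units with the lowest index, from -4.78 to -3.49, had at most 3 reads in their first 500 bp over both replicates. In all, 37 units (2.13% of the set) had so few.

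The title of the series concerns elongation, and the elongation density index addresses it by comparing the downstream with the upstream part of each body. The index was close to equal on the X and the autosomes with the units called here. Its median was -0.17 on the X and -0.16 on the autosomes, a difference of -0.0042 (95% interval -0.17 to 0.16, permutation p = 0.955). The difference of medians was 0.046 in replicate 1 and 0.016 in replicate 2, while the first value is that of units averaged over replicates. The interval leaves room for a shift of either sign. Units here end at sharp changes of density, and whether that hides a gradient was tested only in part. The difference was 0.012 and 0.017 with ends at changes of more than 1 and more than 3 doublings. It was 0.087 in units without an internal rise. In simulations a planted index difference of 0.3 was recovered as 0.25. That planted difference is small against the change of more than 2 doublings that ends a unit. Its recovery therefore cannot show whether unit ends hide a gradient. No larger difference was planted in the index. The X minus autosome value in the data depended on how units were drawn. Under the 5 settings of the 2-state caller, whose units had median lengths in the set of 21574 to 61392 bp, the X was higher by 0.12 to 0.42, and 1 setting passed the permutation test (0.42, p = 0.00773). In simulations of the level model with no planted difference the test of this index passed in 2 of 10 and 3 of 10 draws, so its p-values may be too small.

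X-linked units with the highest index, among those with at least 200 body reads in each replicate, included 8021968 to 8028200 on the plus strand at 3.13 ± 0.26 (SD, n = 2) and 15828566 to 15841000 on the plus strand at 2.71 ± 0.27. The lowest were 18409530 to 18425200 on the plus strand at -2.44 ± 0.12 and 356880 to 373246 on the minus strand at -2.25 ± 0.040. The 5 highest ran from 2.46 to 3.13 and the 5 lowest from -2.44 to -1.93. Pausing indices ran from -2.59 to 1.16 in the 5 highest, of which 1 was called paused. They ran from -1.44 to 2.85 in the 5 lowest, of which 3 were called paused. Whether such units hold more than 1 start was not tested.

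Along units of at least 6000 bp (205 X-linked and 822 autosomal), the ratio of the X to the autosomal median density was 0.561 ± 0.00058 in the first 500 bp (SD, n = 2). It was 0.643 ± 0.0058 from 500 to 1000 bp, 0.715 ± 0.039 from 1000 to 2000 bp and 0.712 ± 0.0037 from 2000 to 5000 bp. Each region was lower on the X, with adjusted permutation p-values of 8e-05, 4e-05, 0.00015 and 9.33e-05 in that order.

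**Figure D3:**
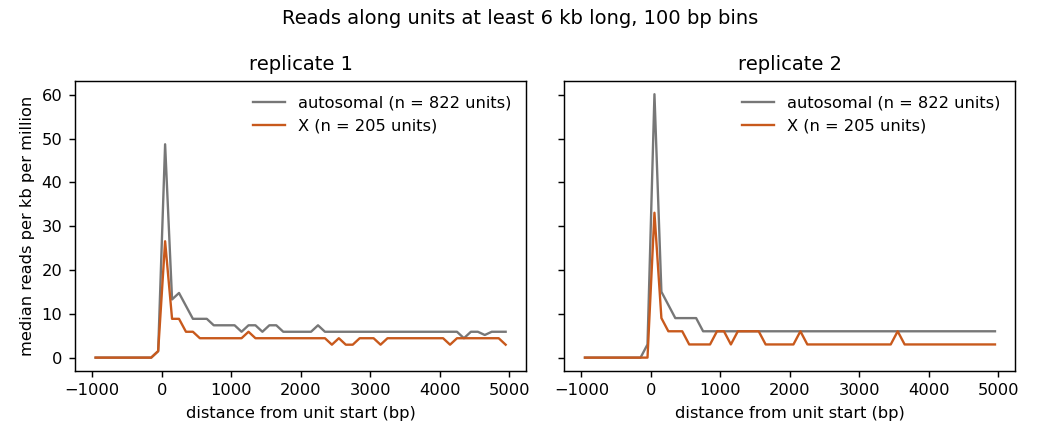
Median read density, in RPKM, in bins of 100 bp around the starts of units at least 6000 bp long, for X-linked (205) and autosomal (822) units in each replicate. Densities peak at the start, where starts were placed by the sharpest rise, and the X line lies at or below the autosomal line; steps in the lines come from whole read counts.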

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

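The test of mismatch limits and the bootstrap of X stretches were chosen after the result was seen. The linear model with GC content and length was planned, but the bounds for this test were set after its result was seen. Gene dosage was raised afterwards and was not tested. Reads outside the compared arms stood above the limit of 3 that a count of 0 allows. This limit is so low for libraries of this depth that passing it says little. Whether these reads were placed correctly was not tested. Chromosome 4 carried 109328 reads over all libraries and a density of 7.89 ± 0.58 RPKM (SD, n = 2), 0.903 of that of the pooled autosomal arms. Heterochromatic and unplaced sequence carried 151208 reads. The Y heterochromatin carried 88 reads, and the mitochondrial genome 186.

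The lower body density of X-linked units (-0.44) was weighed against technical explanations. With at most 2 mismatches per read in every library the difference was -0.45. This outcome was largely set beforehand, since the file of replicate 2 holds no read with more than 2. With replicate 1 left out the difference was -0.43, and it is this value that argues against the unequal mismatch limits of the files. The difference of means was -0.54, and with length and GC content in a linear model it was -0.47, which argues against both as the whole cause. Of 10 stretches of neighbouring X-linked units, 0 had a median at or above the autosomal median. Their differences from it were uneven, from -0.82 to -0.050, and 7 of the 10 had a 95% bootstrap interval below 0. The observed count of 0 met the bound of at most 1 set beforehand against a local stretch, and at least 3 had been set as its mark. The bootstrap interval of the count, added afterwards, ran from 0 to 2, past the bound of 1. Of the draws, 1.3% reached 3 or more. Whether parts of the arm were spared therefore stays open. A lower gene dosage of the X in these cells may also lower its density, and the ratio of 0.669 to the autosomal arms cannot be told apart from it without DNA copy number, so no biological explanation was tested.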

How the results depend on the processing

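The alternatives in unit calling, the mismatch limit, units called in 1 replicate and measured in the other, and the read minima other than 20 and 200 were chosen after seeing the data. Body density stayed lower on the X and past the threshold under all 36 alternatives (-0.70 to -0.36). Promoter-proximal density stayed lower under all 36 (-1.05 to -0.34) and past the threshold under 33. It missed the threshold with the 2-state caller at 100 bp bins and a switch cost of -20 (-0.34) or -40 (-0.59) and at 200 bp bins (-0.47), and the cause was not tested. The pausing index passed the threshold as a difference of means (-0.24), in the linear model with length and GC content (-0.29) and with level changes of more than 3 doublings (-0.35). It was above 0 with the 2-state caller at 100 bp bins and a switch cost of -20 (0.20) and at 200 bp bins (0.012). The difference in the paused share, in percentage points, passed the threshold with reads at 1 position collapsed (-6.48), with level changes of more than 3 doublings (-7.98) and with units called in replicate 1 and measured in replicate 2 (-7.26), and was 1.75 with the 2-state caller at 100 bp bins and a switch cost of -20. The cause was not tested.

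The elongation density index difference (-0.0042) turned positive under 28 of 38 alternatives and passed the threshold under 1. With the 2-state caller it was 0.17, 0.15 and 0.42 at 100 bp bins and switch costs of -10, -20 and -40, 0.12 at 50 bp bins and 0.32 at 200 bp bins. Within the level model it was 0.12 with 100 bp bins, 0.012 and 0.017 with changes of more than 1 and more than 3 doublings, 0.068 with a switch cost of -15 and 0.0020 with starts at bin edges. It was 0.12 with units called in replicate 1 and measured in replicate 2, 0.011 in the reverse case, 0.087 in units without an internal rise and 0.013 with a density minimum of 4. It was 0.0043 with a length minimum of 1500 bp, 0.017 with collapsed reads, 0.017 with units close to an upstream unit, 0.036 with a narrower promoter-proximal window, 0.010 without lane 2 of replicate 1, 0.024 without arm 2R and 0.0060 without arm 3R. It was 0.0074 with 0.5 reads added, 0.0022 with the body split at its middle, 0.040 as a difference of means, 0.097 in the linear model and 0.076 matched on body density. Without replicate 1 or 2 it ran from 0.010 to 0.017. All values of the level model lay within the 95% interval of -0.17 to 0.16.

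The difference in transcribed windows was -0.88 points with a minimum of 1 RPKM and ran from 1.28 to 1.64 points with either replicate left out. The Spearman correlation of the replicates was 0.981 in windows with at least 50 reads. The filter on annotated starts, mappable length, gene lists and exon against intron density were not run. No alternative measured DNA copy number, and 2 replicates limit the precision of each unit's error.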

Other observations

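Several tests were not planned and were chosen after other results had been seen. These covered downstream over promoter-proximal density in long units, the initiator and its reverse complement and the replicate shift in pausing. The CA repeat control and the comparison of motifs within strata of reads were also among them. Start sequences were read from the bases that the reads themselves covered, for 1400 units of the set. This coverage was unequal, with 836 of 911 paused units (91.8%) and 564 of 825 others (68.4%) searched, and the searched units had medians of 266.5 and 77.5 reads in their first 500 bp. The initiator core TCAGT was found most often with its first base 2 bases upstream of the most frequent read 5′ end, in 20 units (1.43%), against at most 6 at any other tested offset. Its reverse complement was found in at most 6 units at any tested offset. It lay near the start in 2.75% of 836 paused units and 0.53% of 564 others (odds ratio 5.29, Fisher's exact p = 0.00199, adjusted p = 0.00597). Within 5 strata of reads in the first 500 bp the odds ratio was 2.92 and missed the threshold (permutation p = 0.214), so whether it differs by pausing stays open. These reads also enter the pausing call, and few units of unlike pausing shared a stratum at the extremes.

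A pause button, the motif KCGRWCG downstream of the start, was tested as a mark of paused units. It lay 10 to 70 bases downstream in 5.50% of paused units and 2.84% of others, with an odds ratio of 1.99 (Fisher's exact p = 0.0172, adjusted p = 0.0258), and in a window from 60 to 120 bases the odds ratio was 1.21 (p = 0.623). Shuffling the bases within each window gave a mean odds ratio of 1.11 with an SD of 0.40, and 3 of 100 shuffles reached the observed value. Within the 5 strata of reads the odds ratio was 0.915 (permutation p = 0.852) and 61 of 100 shuffles reached it. Without strata the mean shuffled ratio lay below the observed one by more than its SD, the bound set beforehand against base composition. At like numbers of reads near the start the excess in paused units was itself not seen, so the bound could not be applied there. Those reads also enter the pausing call, so the strata cannot decide either, and neither the motif nor base composition was settled. The motif was present in few units of either class.

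Reads on the opposite strand upstream of starts were few. In the 500 bp before the start, antisense density was 2.94% of promoter-proximal sense density in the median unit, below the 10% set beforehand as the mark of widespread divergent initiation, and 36.2% of units lay above 10%. The median was 5.01% on the X and 2.58% on the autosomes, a difference that was not tested.

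GA-repeat octamers were denser in read-covered X sequence than on the autosomal arms, with a ratio of 1.88 to the autosomes and ratios from 0.872 to 1.07 among the autosomal arms. CA-repeat octamers had a ratio of 1.92 on the X, so the excess was not specific to GA repeats.

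In units of at least 6000 bp, the log2 ratio of density at 2000 to 5000 bp over that in the first 500 bp was -1.01 on the X and -1.41 on the autosomes. The difference of 0.40 had a permutation p of 0.0206, while its 95% bootstrap interval ran from -0.057 to 0.75. It was 0.30 in replicate 1 and 0.56 in replicate 2. The first 500 bp are also the promoter-proximal window, so this ratio is close to the pausing index with its sign turned. It does not measure a gradient within the body. In units of at least 5000 bp the pausing index difference was -0.15 and did not pass the permutation test (p = 0.362).

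The pausing index was higher in replicate 2 than in replicate 1 in 65.8% of units, with a median difference of 0.17, and the median difference was 0.16 with at most 2 mismatches per read.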
